A study of Brassica napus with 6 samples.

How the data were processed

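RNA sequencing libraries were made from microspore cultures of Brassica napus (oilseed rape), all from DH-4079, a line of cultivar Topas. Brassica napus is an allotetraploid that carries an A and a C genome, so many of its genes have a close homoeologous copy. The 6 libraries fall into 2 groups of 3 in the sample labels. The VM group holds vacuolated microspores (late unicellular microspores) at day 0, before stress. The HS4d group holds cultures kept at 32 °C from their start until day 4, when they contained microspores and proembryos. The series describes its replicates as biological.

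The authors deposited a table of raw counts per gene for the 6 libraries, with 104573 rows. The authors also deposited a table of log2-like values from a variance-stabilising transformation (VST) of counts, with 76486 rows and, in the copy used here, columns for 5 libraries. HS4d replicate 3 has no column in that copy. Every row absent from the transformed table had a total of 10 or fewer counts over the 6 libraries, but 4194 of its rows had such totals too, so the row filter is not known. Applying DESeq2's transformation to these counts in 4 ways (6 or 5 libraries, blind to the groups or not) did not return the deposited values, with a median absolute difference of at least 0.386 on the log2 scale, and the settings behind them are not given in the sources used here. Per the submitters' processing notes, the tools were fastp 0.22.0, HISAT2 and DESeq2. The counting program, genome build, annotation and treatment of reads that map to several places are not given in the sources used here. Per the labels' protocols, the libraries were non-directional and were sequenced as paired ends. Reads from a gene and an antisense partner, or from near-identical homoeologues, could therefore be divided or merged in ways that the counts do not show.

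The identifiers in the files begin with GSBRNA2T or ENSRNA. The files do not pair them with gene names, and 0 of them were found in the reference gene table of the Da-Ae assembly. The 26 gene lists planned before the data were examined, which rested on product names and included markers of tapetum, green tissue, late pollen and sperm cells, were therefore not analysed here. No coordinates, gene lengths or GC contents were used. The rule for named genes, also fixed before the data were examined, allowed in this case the 2 largest rises and the 2 largest falls among genes with an adjusted p under 0.05, a mean of at least 5 on the log2 CPM scale (counts scaled to the library size) and no overlap between the groups.

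The groups were compared with edgeR 4.0.16 and limma 3.58.1 in R 4.3.3. Genes were kept by filterByExpr with its minimum count of 10, which left 56949 genes and removed 47624. Counts were scaled by TMM factors, dispersions were estimated, and HS4d was tested against VM by the quasi-likelihood F test with group as the only term. P-values were adjusted by the Benjamini-Hochberg method, and an adjusted p under 0.05 is called a change. Standard errors of log2 fold changes were taken as the absolute fold change divided by the square root of F. A count with a size limit, a fitted fold of at least 2, was fixed beforehand as a second result. Log2 CPM values for correlations and principal components used a prior count of 1. CPM values of single genes were scaled by TMM, while shares of a library's counts and groups defined by CPM used the library total. Measures of single libraries were compared by a two-sided exact permutation test, in which 3 libraries against 3 cannot give a p below 0.1. The groups of genes defined by abundance or by near absence in a group were chosen after the data were seen.

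Total counts ranged from 29144220 to 39558658 per library, so that 3 counts corresponded to 0.0758 to 0.103 CPM. Limits from such floors, and ratios with exact 95% intervals (Clopper-Pearson), cover counting error only, since reads without molecular identifiers are not independent molecules. No pair of libraries agreed within sampling noise. The chi-square per degree of freedom was 9.38 for the closest pair, VM replicates 2 and 3.

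Where HS4d replicate 3 was compared with genes called without it, an unchanged library was simulated from the VM means and dispersions at its depth. For the signs and correlations over all tested genes, every library was simulated so, VM included. The test was checked on simulated counts with the means, library sizes and trended dispersions of these libraries and 50 changed genes at each fold size. With all 6 libraries and 56949 genes, it recovered 0 of 50 genes changed 2-fold, 6 of 50 changed 4-fold, 18 of 50 changed 8-fold and 44 of 50 changed 32-fold, with 2 false calls. With HS4d replicate 3 left out and 61116 genes, it recovered 25, 47, 49 and 50 of 50, with 13 false calls. The changed genes were a far smaller share than the real calls and were drawn only from genes above a lower limit of mean CPM. These rates are therefore not the power of the real test and do not cover the least abundant genes.

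Alternatives were other scalings (DESeq2 1.42.0 size factors, upper quartile, library size alone), no filter on low counts, a stricter filter (5 CPM in at least 3 libraries), the DESeq2 Wald test, limma-voom, limma on the transformed values, the replicate number as a block, a test against a 2-fold change (glmTreat), and leaving out each library. The same genes were kept when a library was left out. Robust dispersions, a recomputed filter without HS4d replicate 3, and library sizes without the 100 most abundant genes of each library were added after the data were seen.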

Results

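Microspores are the immature male gametophytes of flowering plants, and heat can turn them from pollen development towards forming embryos in culture. The series compared 3 VM libraries of Brassica napus (vacuolated microspores, day 0) with 3 HS4d libraries (cultures at 32 °C, day 4). No library here is from an unheated day 4 culture, so heat, time in culture and development cannot be told apart. Total counts were 31689399, 32861160 and 33375742 in VM replicates 1, 2 and 3. They were 29144220, 39558658 and 31967898 in HS4d replicates 1, 2 and 3. Between 69743 and 73624 genes had at least 1 count in each library.

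The VM libraries were close to one another, with Pearson correlations of log2 CPM across the 56949 tested genes of 0.975 to 0.98. HS4d replicates 1 and 2 were also close to each other, with a correlation of 0.965. HS4d replicate 3 was not close to any library. It correlated at 0.623 and 0.596 with HS4d replicates 1 and 2, and at 0.516 to 0.524 with the VM libraries. Which group it resembled more depended on how the values were prepared. With the offset and the set of genes both changed, to log2(CPM + 1) over all rows, it correlated at 0.699 and 0.693 with the other HS4d libraries and at 0.795 to 0.802 with VM. Genes are not independent replicates, so these correlations carry no p-value. Its total count lay within the range of the other libraries.

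**Figure D1:**
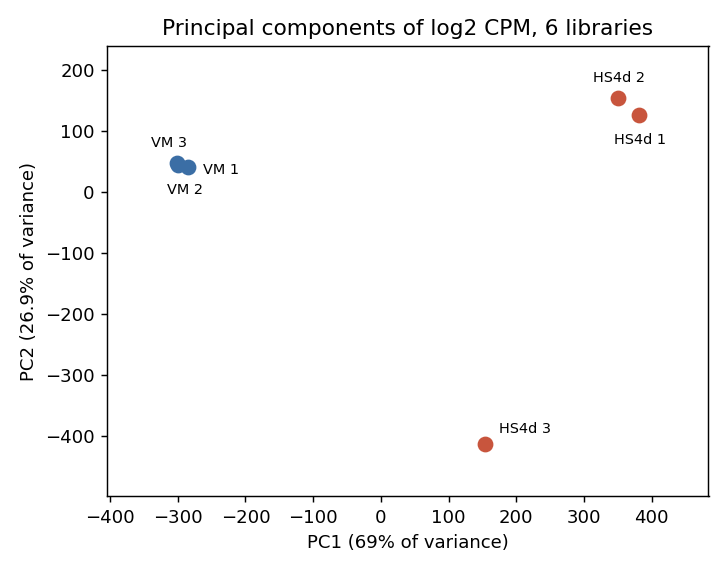
Each point is 1 library, placed by the first (PC1, 69% of variance) and second (PC2, 26.9%) principal components of log2 CPM over the tested genes. The 3 VM libraries and HS4d replicates 1 and 2 lie apart along PC1, and HS4d replicate 3 is separated from all others along PC2, at -413.

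The most abundant genes at day 4 were almost all different from those at day 0. The 100 most abundant genes of HS4d replicates 1 and 2 had 90 genes in common. These 90 genes held 35.0% and 36.9% of all counts in those libraries, 0.123% to 0.169% in the VM libraries and 0.39% in HS4d replicate 3. The 100 most abundant genes of each of these HS4d libraries shared at most 1 gene with those of any VM library. The 100 most abundant genes of HS4d replicate 3 shared 1 gene with those of each other HS4d library and 11 to 14 with those of the VM libraries.

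Counts were also concentrated on fewer genes in the heated cultures. The 100 most abundant genes of each library held 7.48% ± 0.75 (SD, n = 3) of the counts in VM and 28.8% ± 14.9 (SD, n = 3) in HS4d. The values were 36.3%, 38.4% and 11.7% in HS4d replicates 1, 2 and 3, each above every VM library. The effective number of genes, the exponential of the Shannon entropy of the count shares, was 18488 ± 790 (SD, n = 3) in VM. It was 3724, 3558 and 15776 in HS4d replicates 1, 2 and 3. For both measures the two-sided exact permutation test gave p = 0.1, the smallest that 3 libraries against 3 allow.

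**Figure D2:**
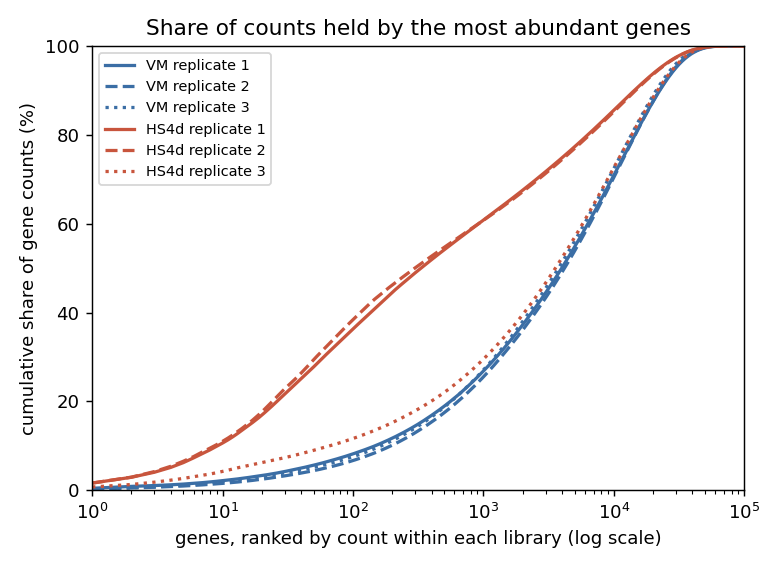
The curves give the cumulative share of a library's counts (vertical axis, %) held by its most abundant genes (horizontal axis, rank on a log scale) for the 3 VM (blue) and 3 HS4d (red) libraries. At rank 100 the curves of HS4d replicates 1 and 2 stand at 36.3% and 38.4%, HS4d replicate 3 at 11.7% and the VM libraries at 6.69% to 8.19%.

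Between VM and HS4d, 16327 of the 56949 tested genes (28.7%) changed. Of these, 9858 rose and 6469 fell in the heated cultures (edgeR quasi-likelihood test, Benjamini-Hochberg adjusted p under 0.05). The median fitted log2 fold change was 3.51 among the genes that rose and -2.68 among those that fell. These medians cover called genes only, and the test recovered few small changes in simulated data (0 of 50 genes changed 2-fold and 6 of 50 changed 4-fold). Only 50 genes per fold size were changed in the simulation, a far smaller share than was called here. Its adjusted threshold was therefore stricter, so these rates are not the power of the test on these data. At least 2-fold changes made up 15633 of the calls, 9546 of them rises and 6087 falls. At least 32-fold changes were fitted for 3322 genes that rose and 1097 genes that fell. A fitted fold pools the HS4d libraries, so a large rise can be near absent in HS4d replicate 3, as in the named rises below. How many of the large rises were so was not counted. The 3 HS4d libraries did not overlap the 3 VM libraries for 29672 tested genes (52.1%), where chance gives 10% on average. Genes vary together, so a single split can lie far from that average without a group effect. Where VM had no counts, a trace of counts in HS4d replicate 3, which carry-over could give, is enough for no overlap.

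These counts depended on which libraries were included. Without HS4d replicate 3, 20220 of the same 56949 genes rose and 21365 fell, and 15958 rose and 16741 fell at least 2-fold (edgeR quasi-likelihood test, adjusted p under 0.05). Of the 16327 genes called with all libraries, 16310 were called in the same direction without it. Leaving out any other single library lowered the count of changed genes, to between 3014 (without VM replicate 2) and 10599 (without HS4d replicate 2). The majority of rises did not hold in every fit. Rises made up 60.4% of the calls in the test with all libraries, 48.6% without HS4d replicate 3, 48.6% with limma-voom and 33.7% with library size alone in place of TMM. Library size alone moved the median log2 fold change of all tested genes from 0.07 to -0.78, and the directions given here are relative to the TMM scale.

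**Figure D3:**
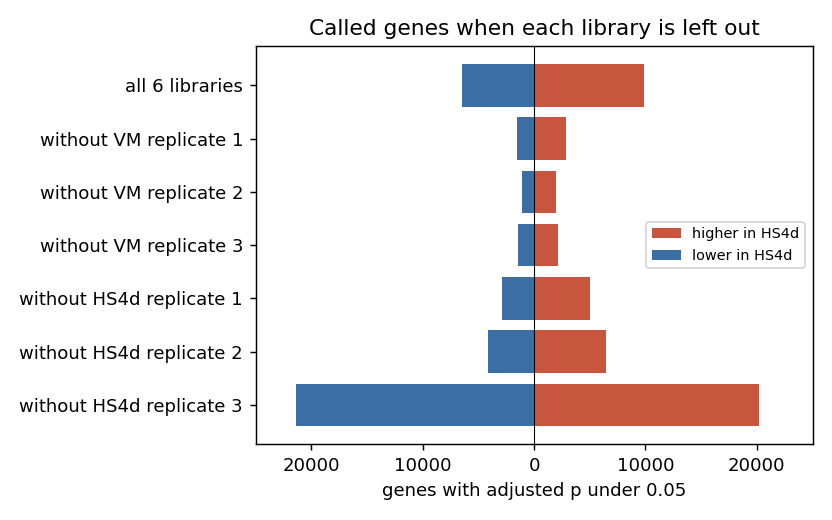
Bars give the number of genes with an adjusted p under 0.05 that were higher (red, right) or lower (blue, left) in HS4d, with all 6 libraries and with each library left out. Leaving out HS4d replicate 3 gave 20220 rises and 21365 falls, against 9858 and 6469 with all libraries.

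The genes that were nearly silent in one group and well expressed in the other formed a small set. In 96 genes, each HS4d library had at least 10 CPM while the VM libraries together had 3 counts or fewer. They held 2.99%, 3.08% and 3.20% of the counts in HS4d replicates 1, 2 and 3. By library totals, their median abundance was 30.0 CPM in HS4d replicates 1 and 2 and 95.7 CPM in HS4d replicate 3. The TMM factors of HS4d replicates 1, 2 and 3 (0.55, 0.567 and 1.184) would narrow this gap. The opposite set, with at least 10 CPM in each VM library and 3 counts or fewer over the HS4d libraries, held 22 genes. They made up 0.044% to 0.051% of the counts in VM.

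A larger set of genes, absent or nearly so from VM, was well expressed in HS4d replicates 1 and 2. In 787 genes, which include the 96, both of these libraries had at least 10 CPM while VM together had 3 counts or fewer. They held 11.2% and 9.73% of the counts of HS4d replicates 1 and 2 and 3.25% of those of HS4d replicate 3, where their median was 0.28 CPM. The opposite set, with at least 10 CPM in each VM library and 3 counts or fewer over HS4d replicates 1 and 2, held 27 genes. The filter on low counts kept 393 of the 787. A further group within the 787, of 201 genes with 3 counts or fewer over VM and HS4d replicate 3 together, did not pass that filter and was not tested.

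The 2 genes with the largest rise by the fixed rule were GSBRNA2T00142852001 and GSBRNA2T00026105001, whose products the files do not name. GSBRNA2T00142852001 had 0 counts in each VM library and 3332, 3786 and 13.5 CPM in HS4d replicates 1, 2 and 3. Its counts pooled over the HS4d libraries were at least 81568-fold higher, relative to scaled library size, than the limit of 3 counts over the VM group (edgeR adjusted p = 0.0387). GSBRNA2T00026105001 also had 0 counts in each VM library, with 2059, 2425 and 14.1 CPM in HS4d replicates 1, 2 and 3. Its pooled counts in HS4d were at least 51661-fold higher than that limit (edgeR adjusted p = 0.0321). Carry-over between libraries could also give such low values in HS4d replicate 3, on which the absence of overlap rests. For these genes the size rests on HS4d replicates 1 and 2. Their calls were lost when any library but HS4d replicate 3 was left out, with edgeR adjusted p up to 0.117 and 0.0987. The fitted log2 fold changes hardly moved in those fits, which had fewer libraries. They were 18.95 to 19.28 for GSBRNA2T00142852001 (19.35 with all libraries) and 18.26 to 18.61 for GSBRNA2T00026105001 (18.68 with all libraries).

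The 2 genes with the largest fall were GSBRNA2T00136969001 and GSBRNA2T00021451001. GSBRNA2T00136969001 stood at 69.3 ± 11.9 CPM (SD, n = 3) in VM and had 1 count in all over the 3 HS4d libraries. The ratio of pooled counts, VM to HS4d, was 5168, with an exact 95% counting interval from 927 to 204144 (edgeR log2 fold change -12.05 ± 0.69 SE, adjusted p = 0.00424). This SE was derived from F and is tighter than the counting interval, so it understates the uncertainty of the fold. GSBRNA2T00021451001 stood at 66.5 ± 7.54 CPM (SD, n = 3) in VM and had 1, 3 and 0 counts in HS4d replicates 1, 2 and 3. The ratio was 1242, with an interval from 485 to 4561 (edgeR log2 fold change -10.05 ± 0.97 SE, adjusted p = 0.00449). Both falls were present in all 3 heated cultures, which the rule for named genes required. They stayed called without any 1 library, but their fitted sizes moved. The log2 fold change of GSBRNA2T00136969001 was -14.23 without HS4d replicate 3, where no HS4d count was left and the value is no bound. That of GSBRNA2T00021451001 was -11.41 without HS4d replicate 2 and -9.24 without HS4d replicate 3.

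The genes that separated HS4d replicates 1 and 2 from VM were followed in HS4d replicate 3, which was left out of both the filter and the test that chose them. Of the 18229 genes at least 2-fold higher in that fit, HS4d replicate 3 lay above every VM library for 63.2% and below every VM library for 22.4%. A simulated unchanged library gave 19.3% and 20.7% for the same genes. It was drawn from the VM means that helped choose the genes, so it cannot show how much that choice alone raised the 63.2%. A gene with 0 counts in VM stayed at 0 in it, so even trace reads would exceed it. The simulated library scattered only as VM libraries do. It therefore cannot show the shares for a library that differs from VM in ways unrelated to HS4d replicates 1 and 2. The median log2 difference of the 18229 genes from VM was 3.04 in HS4d replicates 1 and 2 and 1.04 in HS4d replicate 3. Of the 17633 genes at least 2-fold lower, HS4d replicate 3 lay below every VM library for 68.0% and above every VM library for 21.2%, against 25.3% and 22.4% for the simulated library. Their median log2 differences were -2.14 and -0.72. Over all tested genes, both differences from VM had the same sign for 65.5% of genes. The share was 59.7% when every library, VM included, was simulated as unchanged from the VM means. Across genes, which are not independent replicates, the differences had a correlation of 0.595, against 0.272 in this simulation. Their covariance was 4.45 on the squared log2 scale, against 0.049. The VM libraries were not divided between the sides. Part of the shared sign, and of the shares above or below every VM library, may therefore come from using the same ones on both sides.

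**Figure D4:**
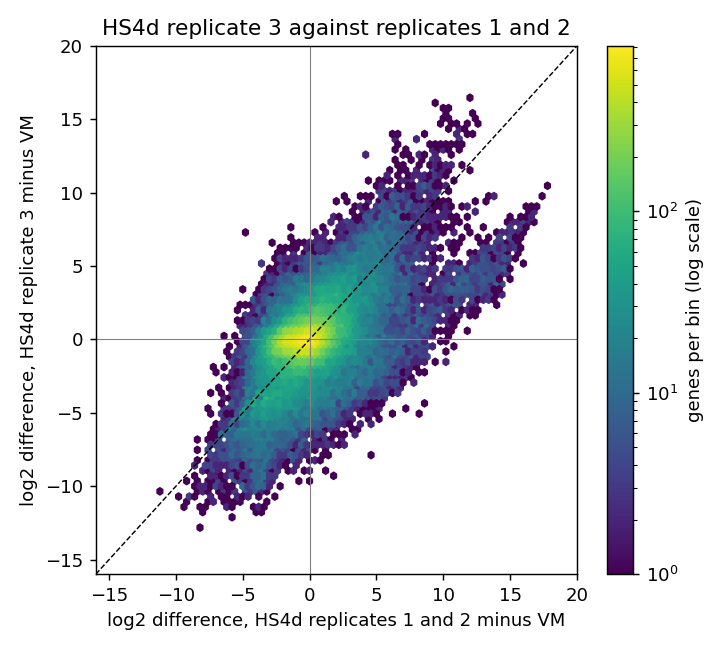
Each hexagon counts tested genes (colour, log scale) by their log2 difference from VM in HS4d replicates 1 and 2 (horizontal axis) and in HS4d replicate 3 (vertical axis), with the dashed line marking equal differences. The differences covary (covariance 4.45), and a separate band of genes with large differences in replicates 1 and 2 lies well below the line.

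Rows with ENSRNA identifiers were a minor part of the data. They held 0.107% ± 0.0038 (SD, n = 3) of the counts in VM and 0.0851% ± 0.0081 (SD, n = 3) in HS4d. Of the 266 tested, 25 rose, 14 fell and 227 were not called. Their median abundance was low, at -0.54 on the log2 CPM scale against 2.53 for the rows with GSBRNA2T identifiers. Of the 56683 tested GSBRNA2T rows, 9833 rose, 6455 fell and 40395 were not called.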

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

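The counts of changed genes moved by over 1.5 times with the choice of libraries, tool and filter. Leaving out 1 library gave 3014 to 41585 changed genes, 1934 to 20220 rises, 1080 to 21365 falls and 3014 to 32699 changes of at least 2-fold. The highest of each came without HS4d replicate 3 and the lowest without VM replicate 2. With the filter also recomputed without HS4d replicate 3, an alternative chosen after seeing the data, 44587 genes changed, 22297 up and 22290 down, and 35862 at least 2-fold. Limma on the deposited VST values, which lack that library, gave 43146 changes, 18078 up and 25068 down, and 29607 of at least 2-fold on the VST scale. The DESeq2 Wald test gave 24526 changes with 10252 falls, and for 1198 genes it gave no adjusted p. The stricter filter, which tests fewer genes, gave 7421 changes, 4296 up and 3125 down, and 6542 of at least 2-fold. The test against a 2-fold change gave 9124 changes, 5934 up and 3190 down. Library size alone gave 5241 rises and 10318 falls, and 161 of the 16327 main calls turned their sign. Limma-voom gave 6986 rises and 7394 falls. The cause of the other shifts was not tested. Among the genes each tested, no main call turned its sign in any other fit (not counted for glmTreat).

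The replicate numbers showed no pairing of the libraries: correlations of the deviations from the group means were -0.012, -0.035 and -0.036 for numbers 1, 2 and 3. HS4d replicate 3 set most of the deviations in its group, so this check could have missed a pairing. With the replicate block, 4666 genes changed, 3314 up and 1352 down, all 4666 at least 2-fold. The rises of GSBRNA2T00142852001 and GSBRNA2T00026105001 were then not called (adjusted p = 0.111 and 0.0882). Both named falls stayed called in all 18 alternatives that gave them a value, and both named rises in 12 of 18. Summing counts over genes with 1 product name and the gene list tests were not run, because no product names were at hand. The effect of depth on the counts of calls was not tested, and 3 counts corresponded to 0.0758 to 0.103 CPM. Of the 10 splits of the libraries into 3 and 3, only the real one, 1 split, called genes: 16327 changed and 15633 at least 2-fold, against 0 as the highest of the others. With 10 splits the share cannot fall under 0.05. Every other split puts VM and HS4d libraries on the same side, which widens the spread within sides. The 0 calls there are therefore no evidence for the real grouping.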

Other observations

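The tests in this part on label swaps, depth, the low counts of abundant genes and the 3 alternatives added to the plan were chosen after the results were seen. For the mixture test and the test of library sizes without the most abundant genes, the prediction was written before the value it measures was seen, though after the patterns that prompted them.

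HS4d replicate 3 had its own set of abundant genes. At 10 CPM or more, 2572 of the tested genes (4.52%) were at least 4 times as high in HS4d replicate 3 as in the highest of the other 5 libraries. They held 22.6% of its counts. The same criterion was met by at most 4 genes in any other library, although each of those has a close partner that makes this harder to meet. Only 9 genes reached 10 CPM in HS4d replicate 3 with 3 counts or fewer over all other libraries.

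HS4d replicate 3 stood apart from the other heated cultures. Leaving it out raised the count of changed genes from 16327 to 41585, while leaving out any other library lowered it, to 3014 at the lowest (without VM replicate 2). A mixture of RNA from the 2 groups lies between its sources, and the 2572 genes far above both argue against it as the whole cause. A swap with a VM library needs a VM library out of place, but the lowest correlation among the VM libraries was 0.975 and their highest with HS4d replicates 1 and 2 was 0.46. Low depth is argued against by its total of 31967898 counts, within the range of the others. A culture that differed in stage or in its share of responding cells, a library from outside the series, and a difference in RNA quality or batch remain open and were not tested.

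The 90 genes that led both HS4d replicates 1 and 2 were present in HS4d replicate 3 at a low level. By library totals without TMM, the median ratio of HS4d replicate 3 to the mean of replicates 1 and 2 was 0.821%. HS4d replicate 3 was above every VM library for 77 of the 90 genes. Reads assigned to wrong libraries alike across the series would give VM a similar ratio, but the VM median was 0.0149%. One small share of RNA or reads like those of replicates 1 and 2 may be a candidate explanation: the 90th percentile of the ratio was 2.74 times the 10th, between the limits set for an even (2) and an uneven (4) ratio, against 1.57 for replicate 1 over replicate 2. Over genes at 0 counts in VM, of which only 4 were abundant enough to compare, it was 1.62 times. Whether such a share came from a few responding cells or from carry-over between these libraries cannot be told apart, because each would give one even ratio.

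Most calls were rises with TMM (60.4%) and falls with library size alone (33.7% rises), but scaling was not the only choice that turned the majority. Rises made up 48.6% of the calls without HS4d replicate 3 and also 48.6% with limma-voom, both scaled by TMM. A prediction took the 100 most abundant genes of each library as the cause. Leaving them out of the library sizes should then move the share of rises by over 10 percentage points towards the TMM share. The share moved from 33.7% to 42.6%, with 6958 rises and 9390 falls, short of that limit and of the 60.4% with TMM. These genes therefore account for part of the gap at most. Broader shifts in abundance below the top 100 remain open, and total RNA per cell was not measured in these files.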
